A study of Mus musculus with 24 samples.

How the data were processed

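The series holds RNA sequencing of whole lung from mice on a control or a docosahexaenoic acid (DHA)-rich diet that breathed filtered air or ozone, with 6 libraries in each of the 4 groups and 24 in all. Per the submitters' processing notes, reads were processed in Partek, aligned to the mm39 mouse assembly with STAR and counted per gene with HTSeq. The versions of these tools, the gene annotation and the strand setting are not given in the sources used here. The deposited values are raw counts per gene. They are whole numbers, except that the largest gene was rounded to 3 significant digits, and gene coordinates are given as deposited.

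Library totals ran from 18053493 to 26225630 counts, with group means ± SD, of 21.1 ± 1.26 M counts for control-diet air, 22.8 ± 2.78 for control-diet ozone, 23.3 ± 2.42 for DHA-diet air and 22.3 ± 2.67 for DHA-diet ozone. Groups came from the labels. The replicate numbers were tested as possible pairs: libraries of the same number had a mean correlation of −0.0169 after group means were removed, and 0 of 24 libraries were closest to one of their own number, so the main model has no pairing and the number enters as a block in an alternative. The labels do not say whether the libraries came from separate mice. A planned model with sex as a covariate was not run because the libraries do not split by sex.

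Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15), which left 16153. Counts were scaled by TMM and fitted in edgeR 4.0.16 (R 4.3.3) with quasi-likelihood models of 1 mean per group, 20 residual degrees of freedom. The 5 comparisons were ozone against air on each diet, DHA against control diet in each exposure, and the interaction of diet and exposure. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors are the log2 fold change divided by the root of its F statistic. Levels are counts-per-million (CPM) with TMM-scaled library sizes, and log2 CPM used a prior count of 2. A fold is 2 to the power of the fitted log2 change and so differs slightly from the ratio of mean CPM.

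For 46 gene lists written from general knowledge before the data were examined, members called higher and lower were counted over all genes and with the adjustment made over the list alone. Of these lists 45 were tested, because the deposited file held none of the 13 mitochondrial-encoded transcripts of the other. They were tested against other genes with camera in limma 3.58.1 at a preset correlation of 0.01, again with a correlation estimated from the data, and with fry, which tests whether the genes of a list on balance move one way and does not compare them with other genes. The size of the ozone response on the 2 diets was compared over genes called for ozone averaged over diets, with exact permutation of diet labels within exposure (426888 arrangements). Named genes were chosen by a rule fixed beforehand: the 6 largest changes in each direction among called genes with a mean of at least 5 CPM in the higher group, predicted gene models left out, up to 4 called members of each called list, 2 members of a list without a called gene, and the 5 smallest p-values where few or 0 genes were called. The text names a selection of these, and Clca1 in comparisons outside the rule was singled out after its values were seen.

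The alternatives were RLE scaling, library totals without further scaling, no filter, a filter of 1 CPM in 6 libraries, a replicate block, DESeq2 1.42.0, limma-voom with quality weights, 1 surrogate variable (sva 3.50.0), a fit of the 2 groups alone, an adjusted p under 0.01, a fold of at least 2, and leaving out each library. Added after seeing the data were leaving out control-diet air libraries 1 to 3, control-diet air libraries 4 to 6, and DHA-diet ozone libraries 1 and 2. Tables and figures used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

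The gene tests were tested on simulated data drawn from the 16153 genes in the same step, with 50 genes changed at each fold. At 1.25, 1.5, 2 and 4-fold the share recovered was 54, 78, 94 and 100% for ozone on the control diet, 44, 80, 96 and 98% for ozone on the DHA diet, 42, 66, 92 and 96% for diet in air, 36, 66, 82 and 96% for diet after ozone, and 16, 64, 90 and 100% for the interaction. Unchanged genes called numbered 6, 4, 12, 3 and 7. A list of 20 genes raised 1.3-fold gave a camera p of 7.54e-70, and 2 of 50 unchanged lists had p under 0.05. A simulated response ratio of 0.8 gave a median difference of −0.0517 (simulated −0.0481, permutation p = 0.0005), and a ratio of 1 gave a permutation p = 0.946. In all of these simulations each gene was drawn independently of the others. The camera and response-size results of the simulations therefore do not show how these tests perform where genes move together.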

Results

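Gene expression was measured by RNA sequencing in 24 libraries of mouse lung. The mice had eaten a control diet or a diet rich in docosahexaenoic acid (DHA), a long-chain omega-3 fatty acid, and had then breathed filtered air or ozone, an oxidant gas that injures the airway lining. Each of the 4 combinations of diet and exposure had 6 libraries. The series asks whether a DHA-rich diet changes the inflammatory response of the lung to ozone. Total counts ran from 18053493 to 26225630 per library, and 16153 genes passed the filter on low counts. Levels are given in counts-per-million (CPM, mean ± SD, n = 6 libraries per group) and changes as folds or as log2 fold changes ± SE from 1 model over all 24 libraries. The transcript of Scgb1a1, the secretory protein of club cells, took 9.85 ± 0.993% of all counts in control-diet air, 9.85 ± 1.29% in control-diet ozone, 8.85 ± 0.568% in DHA-diet air and 8.22 ± 1.57% in DHA-diet ozone libraries, where library 1 had 5.51%. The labels do not say whether the libraries came from separate mice, so p-values measure the spread between these libraries.

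In mice on the control diet, ozone raised Retnla, cell cycle genes and some inflammatory cytokine and acute-phase genes. Some genes of fat use lay lower, though the calls of Pdk4 and Pck1 ended without control-diet air libraries 1 to 3. Retnla, a secreted protein of alternatively activated macrophages, rose 12.5-fold (log2 fold change 3.64 ± 0.30, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 3.24e-08), from 68.7 ± 26.01 to 859 ± 381 CPM, with all 6 ozone libraries above all 6 air libraries. Saa3 (5.04-fold), an acute-phase protein, Alb (5.61-fold), the serum albumin transcript, Sprr1a (4.22-fold), a cornified envelope protein of stressed epithelium, and Timp1 (4.09-fold), an inhibitor of matrix metalloproteinases, also rose with no overlap between the groups. Pdk4, a kinase that turns cells from glucose to fat use, fell to 0.412 of its air level, and Gbp4, an interferon-induced GTPase, to 0.459. Across the genome 1442 genes were higher and 1271 lower after ozone by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, of which 104 and 35 changed at least 2-fold, and the median change of the called genes was 1.22-fold. The ozone and air libraries did not overlap in 1254 of the 16153 genes (1170 of them called), which chance gives for 0.216% of genes in 6 against 6. The Retnla gene lies on chromosome 16 at 48662972 to 48664825 in the deposited coordinates of the mm39 assembly, whose counting convention is not given in the sources used here, so either end can be off by 1 base.

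Cell cycle genes formed the group with the smallest camera p in control-diet mice. Of 26 measured, 24 rose and 0 fell (26 adjusted over the list alone), with a median log2 fold change of 1.05, a camera adjusted p of 8.88e-20, and adjusted p = 0.329 with an estimated correlation. The replication helicase subunits Mcm5 (10.4 ± 1.08 to 21.4 ± 2.81 CPM, 2.06-fold) and Mcm2 (1.68-fold) were among them. Inflammatory cytokine and acute-phase genes rose in 11 of 20 (12 adjusted over the list alone; camera adjusted p = 5.64e-07, adjusted p = 0.329 with an estimated correlation). They included Lcn2 (2.47-fold), an iron-sequestering defence protein, Il33 (1.83-fold), an epithelial alarm cytokine, and Osm (2.05-fold), an interleukin-6 family cytokine. Of 14 neutrophil and monocyte chemokines 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.003, adjusted p = 0.329 with an estimated correlation). The monocyte attractant Ccl2 rose 3.78-fold to 2.65 ± 0.634 CPM and Ccl17, a ligand of CCR4 on T cells, rose 2.37-fold. The 1 fall among the chemokines was lost without control-diet air library 3, 4 or 5 or control-diet ozone library 1, 2, 3, 4 or 6, with 4 to 6 higher. Immediate early genes rose in 5 of 14 (5 adjusted over the list alone; camera adjusted p = 3.00e-04, adjusted p = 0.337 with an estimated correlation). Without control-diet air library 3 this count was 3.

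Lipid-making, surfactant and protein-folding genes rose in the same libraries. Of 19 cholesterol synthesis genes 13 rose and 0 fell (17 adjusted over the list alone; camera adjusted p = 1.44e-09, adjusted p = 0.329 with an estimated correlation). They included Fdps (1.54-fold), which makes farnesyl diphosphate, and Cyp51 (1.55-fold), the lanosterol demethylase. Of 17 genes of fatty acid synthesis and desaturation 9 rose (11 adjusted over the list alone; camera adjusted p = 6.87e-06, adjusted p = 0.329 with an estimated correlation). They included Fads1 (1.28-fold), a desaturase of polyunsaturated fatty acids, and Elovl1 (log2 fold change 0.38 ± 0.065), an elongase of very long chains. Alveolar type 2 markers rose in 10 of 14 (12 adjusted over the list alone; camera adjusted p = 3.56e-09, adjusted p = 0.329 with an estimated correlation), with surfactant protein Sftpa1 going from 3142 ± 239 to 4096 ± 247 CPM and the lung chemokine Cxcl15 rising 1.38-fold. Unfolded protein response genes rose in 8 of 16 (9 adjusted over the list alone; camera adjusted p = 1.74e-05, adjusted p = 0.337 with an estimated correlation). They included Sdf2l1 (1.67-fold) and the chaperone Calr (log2 fold change 0.38 ± 0.068), both of the endoplasmic reticulum. NRF2 antioxidant targets rose in 7 of 21 (12 adjusted over the list alone; camera adjusted p = 1.53e-06, adjusted p = 0.406 with an estimated correlation). They included Taldo1 (1.27-fold) and G6pdx (1.35-fold), enzymes of the pentose phosphate pathway. That count was 15 in the fit without DHA-diet ozone library 2, a library outside this comparison that enters the shared estimate of the spread. Genes of extracellular matrix and repair rose in 7 of 22 (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.67e-04, adjusted p = 0.337 with an estimated correlation), with Thbs1, a matrix protein, at 1.80-fold. Alveolar macrophage markers rose in 3 of 16 (4 adjusted over the list alone; camera adjusted p = 0.00566, adjusted p = 0.337 with an estimated correlation). They included the chitinase-like protein Chil3 at 1.84-fold, and 5 rose in the fit without control-diet air library 6.

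Fat, muscle and red cell markers lay lower after ozone on the control diet. Whether the fat and muscle differences reflect tissue taken along with the lung was not tested for ozone. Of 27 PPAR targets and fatty acid oxidation genes 6 fell and 0 rose (6 adjusted over the list alone; camera adjusted p = 0.00566, adjusted p = 0.569 with an estimated correlation). Adipocyte markers fell in 3 of 11 (7 adjusted over the list alone; camera adjusted p = 0.00196, adjusted p = 0.406 with an estimated correlation), with the fat droplet protein Plin4 at 0.546 and Pck1, the gluconeogenic enzyme of liver and fat, at 0.349 of the air level. The adipocyte count was 6 without control-diet ozone library 6, and the Pck1 call ended without control-diet air library 1 (log2 fold change −1.23, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.0663). Cardiac muscle (median log2 fold change −0.32, camera adjusted p = 0.00615, adjusted p = 0.569 with an estimated correlation) and skeletal muscle lists (−0.40, camera adjusted p = 0.0129, adjusted p = 0.406 with an estimated correlation) lay lower than other genes. So did the erythroid (−0.63, camera adjusted p = 0.003, adjusted p = 0.353 with an estimated correlation) and platelet lists (−0.35, camera adjusted p = 0.0381, adjusted p = 0.569 with an estimated correlation; median −0.23 without control-diet air library 3). Their members that fell numbered 2 of 10, 2 of 8, 2 of 5 and 1 of 8, against 5, 3, 4 and 1 adjusted over the list alone. In fits without 1 library these counts ran from 0 to 3 (0 for cardiac muscle without control-diet air library 1 or 2), 0 to 3, 2 to 4 (4 without DHA-diet ozone library 4 or 6) and 0 to 3 (3 without control-diet air library 2). Of 14 endothelial markers 2 fell (2 adjusted over the list alone; camera adjusted p = 0.00625, adjusted p = 0.485 with an estimated correlation), 1 of them Sox17, a transcription factor of arterial endothelium, at 0.742 of the air level. Of 18 interferon response genes 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.0446, lower, adjusted p = 0.598 with an estimated correlation). The antiviral gene Rsad2 fell to 0.632, while the counts of falling genes were 1 without control-diet air library 1, 1 without control-diet ozone library 3 and 4 without DHA-diet ozone library 5. Calml3, a calmodulin-like protein of epithelium, fell to 0.504 of its air level.

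Clca1, a goblet cell protein of mucus, rose 5.76-fold on the control diet (log2 fold change 2.53 ± 0.71, edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.0147), but its ozone libraries ran from 0.309 to 88.3 CPM. Without control-diet ozone library 6 its log2 fold change was 1.63 (adjusted p = 0.101 in the same edgeR test). Control-diet air libraries 1 to 3 stood apart from the other air libraries: their ribosomal protein transcripts averaged 7.30, 7.30 and 7.27 log2 CPM against 7.62, 7.65 and 7.68 in libraries 4 to 6. Without these 3 libraries, a choice made after seeing the data, 852 genes were higher and 951 lower. The camera calls for chemokines (adjusted p = 0.099), alveolar macrophages (0.11), PPAR targets (0.723), cardiac (0.229) and skeletal muscle (0.107), platelets (0.099) and the interferon response (0.1) then ended, as did the calls of Pck1, Pdk4, Calml3, Rsad2 and Clca1. The calls of G6pdx and Sox17 ended without libraries 4 to 6, and that of Clca1 also with limma-voom. With library totals and no further scaling, 940 genes were higher and 1737 lower.

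**Figure D1:**
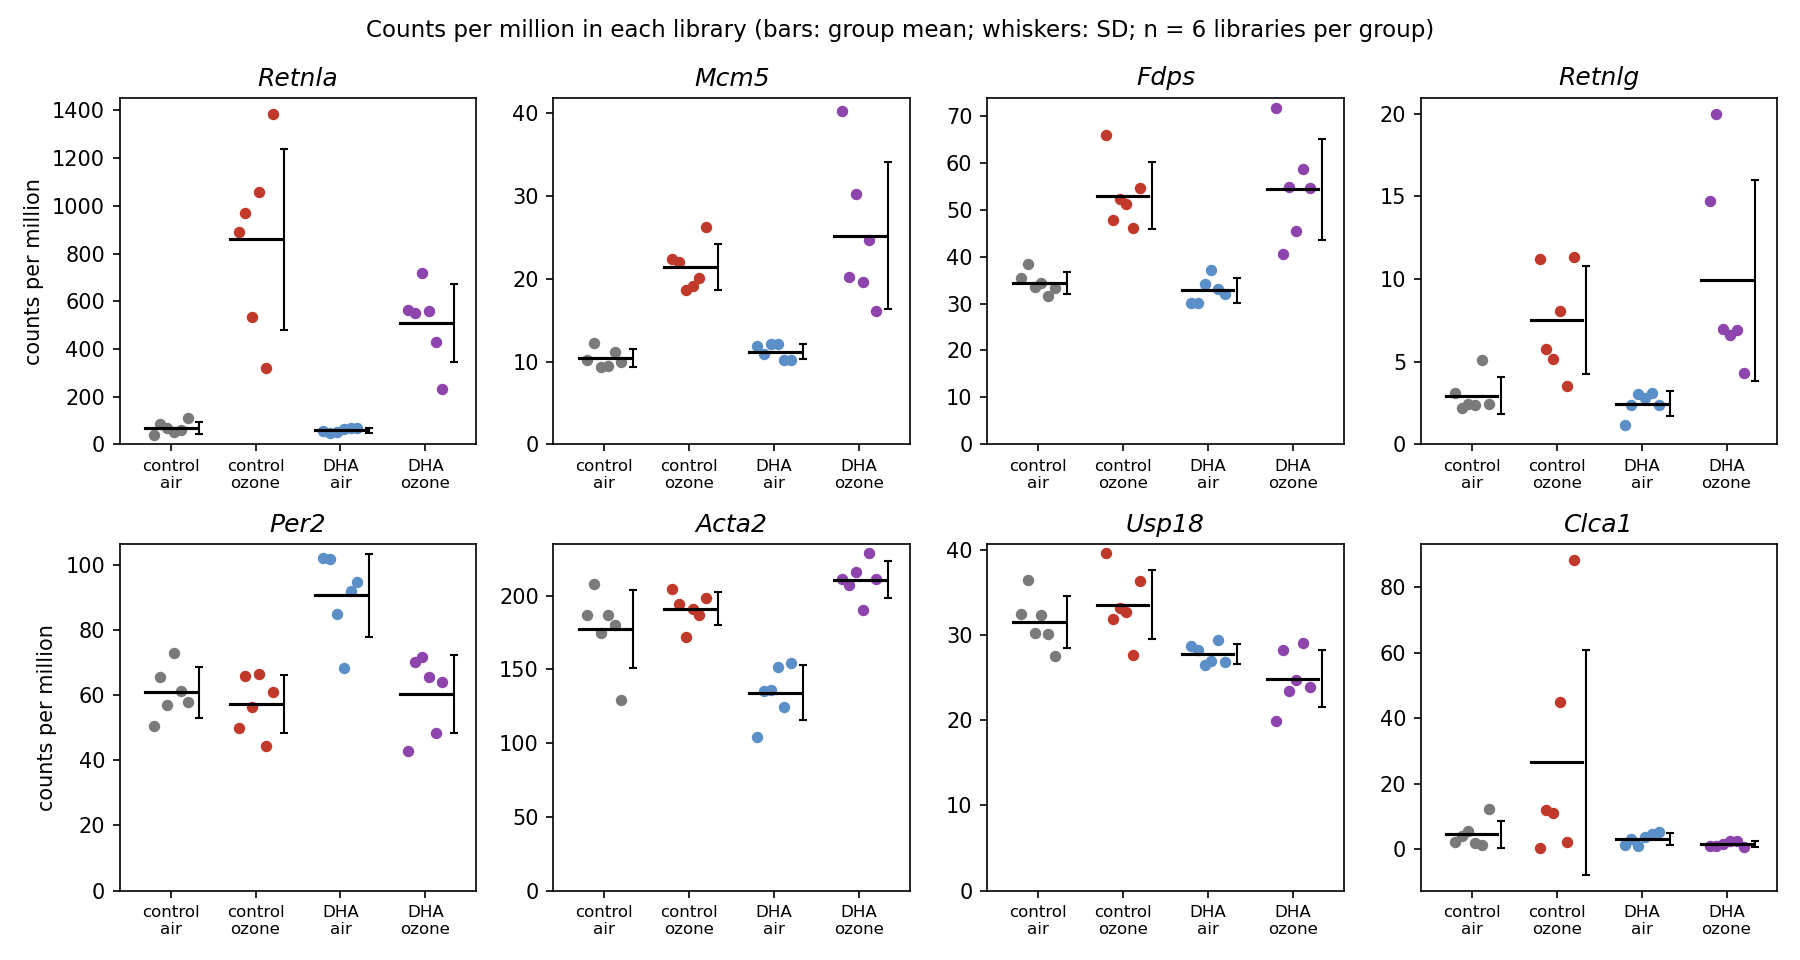
CPM of 8 genes in each of the 24 libraries, with a panel per gene, the 4 groups of diet and exposure on the horizontal axis, a black bar at the group mean and whiskers of 1 SD (n = 6 libraries per group). Retnla reached 320 to 1385 CPM in control-diet ozone libraries against at most 110 CPM in control-diet air, while Clca1 spread from 0.309 to 88.3 CPM within the control-diet ozone group.

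In mice on the DHA diet, ozone also raised Retnla, cell cycle genes and some inflammatory cytokine and acute-phase genes, and neutrophil markers stood highest in ozone libraries 1 and 2. Retnla rose 8.72-fold, from 58.4 ± 9.90 to 509 ± 164 CPM, Sprr1a 8.11-fold, Alb 6.56-fold and Timp1 4.42-fold, each with all 6 ozone libraries above all 6 air libraries. Saa3 rose 7.05-fold (log2 fold change 2.82), and by 1.91 on the log2 scale without DHA-diet ozone library 1, which held 64.1 CPM. Pbk, a mitotic kinase, rose 4.24-fold. Prr33 (to 0.422 of its air level) and Bcan, a brain-type chondroitin sulfate proteoglycan (to 0.437), fell in all 6 ozone libraries below all 6 air libraries, and Gbp4 fell to 0.504 of its air level. In total 2055 genes were higher and 1769 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 167 and 65 of them by at least 2-fold. The groups did not overlap in 1459 of the 16153 genes (1412 of them called), against a chance share of 0.216%.

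Every one of the 26 measured cell cycle genes rose on the DHA diet (26 adjusted over the list alone; median log2 fold change 1.15, camera adjusted p = 7.77e-17, adjusted p = 0.394 with an estimated correlation). They included the mitotic kinase Cdk1 (4.88 ± 1.12 to 15.5 ± 7.32 CPM) and Mcm5 (2.25-fold). Inflammatory cytokine and acute-phase genes rose in 14 of 20 (15 adjusted over the list alone; camera adjusted p = 1.42e-07, adjusted p = 0.394 with an estimated correlation). They included Lcn2 at 2.64-fold and Osm at 2.21-fold. Of 14 neutrophil and monocyte chemokines 6 rose (7 adjusted over the list alone; camera adjusted p = 4.63e-04, adjusted p = 0.394 with an estimated correlation). They included Ccl2 at 3.40-fold and Ccl17 at 2.19-fold. Neutrophil markers rose in 10 of 16 (12 adjusted over the list alone; median log2 fold change 1.04, camera adjusted p = 4.63e-04, adjusted p = 0.593 with an estimated correlation). They included Retnlg (2.47 ± 0.730 to 9.93 ± 6.09 CPM) and the lectin receptor Clec4d (2.44-fold). DHA-diet ozone libraries 1 and 2 held the highest neutrophil scores of the 24 libraries (3.72 and 3.41 log2 CPM, against 1.95 to 2.67 in ozone libraries 3 to 6). Without library 2 alone 6 neutrophil markers and 4 NRF2 targets rose, and without both libraries, a choice made after seeing the data, 4 neutrophil markers rose with a camera adjusted p of 0.0796.

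Cholesterol synthesis genes rose in 16 of 19 on the DHA diet (17 adjusted over the list alone; camera adjusted p = 3.43e-11, adjusted p = 0.394 with an estimated correlation). They included Fdps at 1.66-fold and Cyp51 at 1.64-fold. Genes of fatty acid synthesis and desaturation rose in 9 of 17 (10 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0256, adjusted p = 0.691 with an estimated correlation). Unfolded protein response genes rose in 10 of 16 (10 adjusted over the list alone; camera adjusted p = 2.73e-06, adjusted p = 0.394 with an estimated correlation). They included Sdf2l1 at 1.83-fold and Calr at 1.43-fold. Extracellular matrix and repair genes rose in 12 of 22 and fell in 1 (14 and 1 adjusted over the list alone; camera adjusted p = 9.96e-05, adjusted p = 0.446 with an estimated correlation). The matrix glycoprotein Tnc rose 3.66-fold to 28.9 ± 15.8 CPM, Thbs1 1.90-fold and the membrane metalloproteinase Mmp14 1.27-fold. NRF2 targets rose in 9 of 21 (12 adjusted over the list alone; camera adjusted p = 4.63e-04, adjusted p = 0.699 with an estimated correlation). They included Taldo1 at 1.44-fold. Immediate early genes rose in 7 of 14 (7 adjusted over the list alone; camera adjusted p = 0.00104, adjusted p = 0.587 with an estimated correlation). They included Egr1 at 1.58-fold. Chil3 rose 1.82-fold.

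Clock genes shifted after ozone on the DHA diet, where 7 of 17 fell and 2 rose (9 and 2 adjusted over the list alone; median log2 fold change −0.25, camera adjusted p = 0.0213, adjusted p = 0.587 with an estimated correlation). The period genes Per2 (90.7 ± 12.7 to 60.4 ± 11.99 CPM) and Per3 (to 0.672 of its air level) and the repressor Nr1d2 (to 0.785) fell, while Nfil3, a repressor of clock output genes, rose 1.93-fold. Per2 had stood higher in DHA-diet air than in either control-diet group (60.9 ± 7.75 CPM in air, 57.3 ± 8.86 after ozone). The clock list had a median of −0.02 for ozone on the control diet and of −0.05 between the diets after ozone. The counts were 5 lower and 1 higher without DHA-diet air library 1 and the same without DHA-diet ozone library 1, and 7 lower and 1 higher without DHA-diet air library 3. Smooth muscle and pericyte markers rose in 5 of 12 and fell in 1 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0214, adjusted p = 0.587 with an estimated correlation), with the contractile actin Acta2 going from 134 ± 18.5 to 211 ± 12.4 CPM. Interferon response genes fell in 4 of 18 (4 adjusted over the list alone; camera adjusted p = 0.0115, adjusted p = 0.691 with an estimated correlation). They included Ifi44 (to 0.621) and Rsad2 (to 0.696). Without DHA-diet air library 1 the Rsad2 call ended (log2 fold change −0.40, adjusted p = 0.0508 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and without DHA-diet ozone libraries 1 and 2 the Ifi44 call ended, 1 interferon gene fell and camera gave an adjusted p of 0.154. Of 25 enzymes that make or break down oxylipins, the oxygenated fatty acids that include prostaglandins and DHA derivatives, 4 rose and 1 fell (4 and 1 adjusted over the list alone), among them the prostaglandin E synthase Ptges (1.58-fold) and the 5-lipoxygenase partner Alox5ap (1.27-fold). As a list they did not stand apart from other genes (camera adjusted p = 0.265, adjusted p = 0.593 with an estimated correlation). The fall was lost without DHA-diet air library 1, when 4 rose and 0 fell.

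The ozone responses on the 2 diets shared 1074 higher genes (183 for independent lists of these sizes) and 792 lower genes (139 for independent lists), and 1 gene was called in opposite directions. These comparisons have no library in common, though both use 1 estimate of the spread. Across the 4670 genes called on either diet the log2 fold changes had a Pearson correlation of 0.83 and a Spearman correlation of 0.842 over genes, which are not independent replicates, and 95.0% had the same sign. Over all 16153 genes the Pearson correlation was 0.683, the Spearman correlation 0.651 and the share with the same sign 76.3%. Among the 5726 genes called for ozone averaged over diets, the median change in the direction of that average was 0.204 log2 units on the control diet and 0.236 on the DHA diet. The median difference of 0.0279 log2 units lay within what exact permutation of the diet labels within each exposure gives (2-sided exact p = 0.315 over 426888 arrangements, n = 6 per group), with 60.6% of the genes moving further on the DHA diet. In fits without 1 library the difference ran from 0.0149 without control-diet air library 5 to 0.0414 without DHA-diet ozone library 2, and with genes of at least 2-fold change alone it was 0.0712 (exact p = 0.797).

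**Figure D2:**
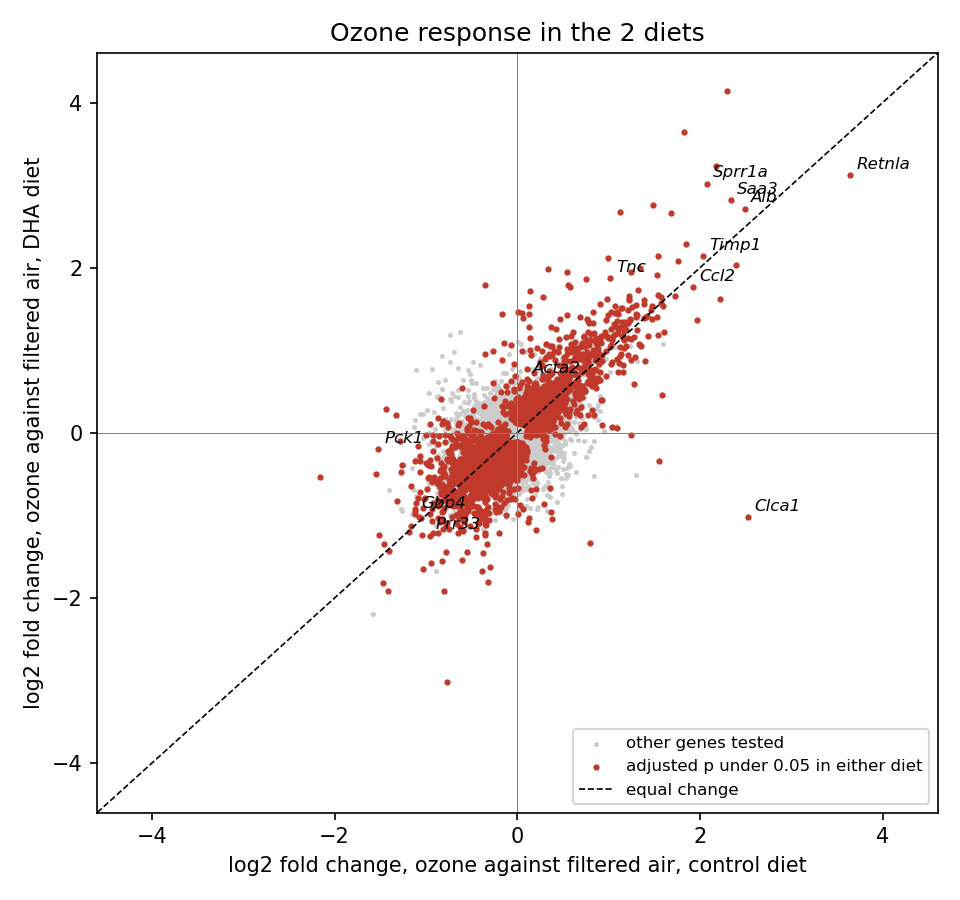
Log2 fold change of ozone against filtered air on the control diet (horizontal axis) and on the DHA diet (vertical axis) for 16153 genes, with genes called on either diet in red and a dashed line of equal change. The Pearson correlation was 0.683 over all 16153 genes and 0.83 over the 4670 red ones, chosen for being called, with Clca1 far below it at 2.53 on the control diet and −1.02 on the DHA diet.

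In filtered air, the DHA diet went with higher levels of some clock, alveolar type 2 and metal handling transcripts. Cys1, a protein of the primary cilium, rose 1.65-fold, from 27.2 ± 3.45 to 44.7 ± 4.83 CPM, with no overlap of the 6 and 6 libraries. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose 1.77-fold (19.98 ± 4.04 to 35.3 ± 9.73 CPM). Tfrc, the transferrin receptor, rose 1.34-fold and Slc30a1, a zinc exporter, 1.19-fold, which were the 2 of 8 metal handling genes called (2 adjusted over the list alone; camera adjusted p = 0.00623, adjusted p = 0.352 with an estimated correlation; 1 called without DHA-diet air library 5). The contractile actin Acta2 fell from 178 ± 26.4 to 134 ± 18.5 CPM. In total 117 genes were higher and 69 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. With muscle and fat marker scores as a covariate 0 were called, and the median absolute log2 fold change of these 186 genes went from 0.34 to 0.23. The groups did not overlap in 299 of the 16153 genes (110 of the 186 called), against a chance share of 0.216%.

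Of 17 clock genes 3 rose with the DHA diet in air and 0 fell (8 and 2 adjusted over the list alone; median log2 fold change 0.28, camera adjusted p = 0.0083, adjusted p = 0.408 with an estimated correlation). Per2 rose 1.49-fold, the repressor Cry1 1.45-fold and Nr1d2 1.32-fold, and the clock count was 1 without control-diet air library 1 and 7 higher with 2 lower without DHA-diet ozone library 1. Alveolar type 2 markers rose in 5 of 14 (9 adjusted over the list alone; camera adjusted p = 1.50e-08, adjusted p = 0.352 with an estimated correlation). They included Etv5, a transcription factor of these cells (1.29-fold), Napsa, a protease that processes surfactant protein B (1.28-fold), and Slc34a2, a phosphate transporter (1.27-fold). That count was 1 without control-diet air library 1, 2 or 4, 2 without DHA-diet air library 3, 4 or 5, 3 without DHA-diet air library 2, and 8 without control-diet air library 5. Among 14 fibroblast markers Dpt, a matrix protein of the dermis and adventitia, rose 1.29-fold and was the 1 gene called (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00156, adjusted p = 0.389 with an estimated correlation), with 0 called without control-diet air library 1 or 2 and 4 without 6. Smooth muscle and pericyte markers fell in 2 of 12 (7 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0339, adjusted p = 0.476 with an estimated correlation). Of 18 interferon response genes 1 fell (5 adjusted over the list alone; camera adjusted p = 8.44e-06, adjusted p = 0.352 with an estimated correlation). Interferon genes that fell numbered 0 without control-diet air library 1 or 2 or DHA-diet air library 2, 3, 4 or 6, 2 without control-diet air library 6 or DHA-diet ozone library 1 or 5, and 5 without DHA-diet air library 1. Smooth muscle genes that fell numbered 0 without control-diet air library 1 or 2 or DHA-diet air library 5. They numbered 1 without control-diet air library 3, 4 or 5, DHA-diet air library 1, 2, 3 or 4, control-diet ozone library 3 or DHA-diet ozone library 3 or 4, 4 without DHA-diet ozone library 1 and 6 without control-diet air library 6.

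Lists of other tissues and of the airway lay lower with the DHA diet in air without a called member. Cardiac muscle markers had a median log2 fold change of −0.44 (8 of 10 lower adjusted over the list alone; camera adjusted p = 9.45e-06, adjusted p = 0.389 with an estimated correlation). Skeletal muscle markers had −0.65 (4 of 8; camera adjusted p = 1.87e-05, adjusted p = 0.352 with an estimated correlation) and adipocytes −0.59 (7 of 11; camera adjusted p = 1.87e-05, adjusted p = 0.352 with an estimated correlation). Ciliated cells had −0.29 (8 of 14; camera adjusted p = 8.44e-06, adjusted p = 0.46 with an estimated correlation). Ciliated scores were 6.30, 6.47 and 6.35 log2 CPM in control-diet air libraries 1 to 3, and 6.20, 6.12 and 5.91 in libraries 4 to 6. They ran from 5.82 to 6.13 in DHA-diet air. Adipocyte scores of the same 2 sets overlapped (3.95, 3.66 and 3.52 against 3.86, 3.30 and 3.09). Skeletal muscle scores were alike (2.49, 2.40 and 2.15 against 2.39, 2.30 and 2.12). PPAR targets and fatty acid oxidation genes had a median of −0.13 (9 of 27 lower adjusted over the list alone; camera adjusted p = 8.74e-06, adjusted p = 0.389 with an estimated correlation). Their scores were 6.04, 5.97 and 5.86 in control-diet air libraries 1 to 3, 5.80, 5.68 and 5.55 in libraries 4 to 6, and 5.54 to 5.73 in DHA-diet air. Libraries 4 to 6 overlapped DHA-diet air, so this difference rested largely on libraries 1 to 3. The heart myosin Myh6 stood at 738 ± 258 CPM on the control diet and 502 ± 96.2 on the DHA diet, the cardiac troponin Tnnt2 at 322 ± 56.4 and 249 ± 50.6, and the adipocyte factor Cfd at 56.7 ± 7.62 and 37.4 ± 15.5 CPM (edgeR quasi-likelihood Benjamini-Hochberg adjusted p = 0.094, 0.145 and 0.104). Myh6 passed the threshold without control-diet air library 6 (0.0286 in the same edgeR test) and Cfd without DHA-diet air library 3 (0.023). Both also passed with limma-voom with quality weights, and Myh6 without control-diet air libraries 4 to 6. Neither passed without control-diet air libraries 1 to 3. The cardiac muscle score was 7.40, 7.42 and 6.87 log2 CPM in libraries 1 to 3, 6.90, 6.89 and 6.755 in libraries 4 to 6, and 6.26 to 7.02 in DHA-diet air. Oxylipin enzymes had 0 called of 25 (1 higher adjusted over the list alone; camera adjusted p = 0.689, adjusted p = 0.76 with an estimated correlation). Over the whole genome DESeq2 called 317 genes higher and 272 lower, and limma-voom 408 and 441.

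Many calls for diet in air lay close to the threshold. Without control-diet air libraries 1 to 3, which stood apart in ribosomal protein transcripts, 0 genes were called higher and 0 lower in edgeR's quasi-likelihood test, while without libraries 4 to 6, as many, 655 and 896 were (both choices made after seeing the data). Leaving out single libraries gave 37 higher and 12 lower without control-diet air library 1, 40 and 13 without 2, 77 and 28 without 3, 51 and 41 without 4, and 277 and 439 without 6. It gave 73 and 48 without DHA-diet air library 1, 63 and 39 without 2, 71 and 36 without 3, 72 and 26 without 4, and 41 and 18 without 5. Among ozone libraries, which enter the spread alone, it gave 308 and 346 without DHA-diet ozone library 1, 150 and 118 without 2, and 92 and 47 without 3. The Cys1, Cry1, Etv5 and Tfrc calls held without any single library. Per2 lost its call without control-diet air library 1 (adjusted p = 0.0619 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), Dpt without 1 or 2 (0.0571 and 0.0593), Napsa without 1, 2 or 4 (0.0641, 0.065 and 0.0516), and Slc30a1 without DHA-diet air library 5 (0.0546). In the same test Acta2 lost it without control-diet air library 1 or 2 or DHA-diet air library 5 (0.0621, 0.065 and 0.0591) and with the replicate block, and Fkbp5 without control-diet air library 1, 2 or 4 or DHA-diet air library 5 or 6 (0.0954, 0.0699, 0.0686, 0.101 and 0.0507). Slc34a2 lost it without control-diet air library 1, 2 or 4 or DHA-diet air library 3, 4 or 5 (adjusted p from 0.0505 to 0.0787 in edgeR's test with Benjamini-Hochberg adjustment). Nr1d2 lost it without control-diet air library 1 or 3 or DHA-diet air library 1, 2, 3 or 5 (0.0505 to 0.0755). Where these calls were lost the log2 fold change ran from 0.30 to 0.35 for Slc34a2 (0.35 with all libraries), 0.38 to 0.40 for Nr1d2 (0.40) and 0.68 to 0.83 for Fkbp5 (0.82). With library totals and no further scaling, 72 genes were higher and 113 lower.

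After ozone, 5 genes shared the smallest adjusted p between the diets in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, none of them past the threshold: Usp18 and Eif2ak2, both induced by interferon, Cdc42ep4, Clca1 and Adra2a. Usp18, which trims ISG15 from proteins, stood at 33.6 ± 4.08 CPM on the control diet and 24.9 ± 3.37 on the DHA diet, and Eif2ak2, the kinase that senses double-stranded RNA, at 33.8 ± 2.08 and 26.8 ± 2.60. Cdc42ep4, an effector of the GTPase CDC42, stood at 125 ± 5.70 and 156 ± 18.4 CPM, and for it and Eif2ak2 the 6 and 6 libraries did not overlap. Clca1 stood at 26.4 ± 34.3 CPM on the control diet and 1.51 ± 0.892 on the DHA diet (log2 fold change −4.11 ± 0.80), and Adra2a, an adrenergic receptor, at 5.61 ± 1.83 and 2.63 ± 0.752. Each of these 5 had an edgeR quasi-likelihood Benjamini-Hochberg adjusted p of 0.0793. In fits without 1 library all 5 passed the threshold without control-diet air library 6 (edgeR Benjamini-Hochberg adjusted p = 0.0458) or DHA-diet ozone library 2 (0.0218 to 0.0393). Usp18, Eif2ak2, Clca1 and Adra2a also passed without control-diet ozone library 5 (0.0232 to 0.048 in edgeR's test with Benjamini-Hochberg adjustment). Cdc42ep4, Usp18 and Eif2ak2 passed without DHA-diet ozone library 5 (0.0451 to 0.0499), and Clca1 without control-diet ozone library 1 (0.0115). DESeq2 and the fit without control-diet air libraries 4 to 6 called all 5, and limma-voom called Cdc42ep4, Usp18 and Eif2ak2. Clca1 had a log2 fold change of −3.21 without control-diet ozone library 6. Clca1 lies on chromosome 3 at 144710298 to 144738538 and Usp18 on chromosome 6 at 121222865 to 121247877 in the deposited coordinates.

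By edgeR's quasi-likelihood test 0 genes were called higher and 0 lower with the DHA diet after ozone, with 2260 at an unadjusted p under 0.05, while DESeq2 called 38 and 37 and limma-voom with quality weights 8 and 11. Leaving out 1 library, edgeR called 71 and 73 without DHA-diet ozone library 2, 1 and 6 without DHA-diet ozone library 5, 4 and 6 without control-diet air library 6, 1 and 1 without control-diet ozone library 1, and 0 and 7 without control-diet ozone library 5. Of 99 regroupings of the same libraries, the median had 814 genes at an unadjusted p under 0.05 and the highest 2481, and 2 of 100 groupings, the real one included, had at least 2260. The interferon response list lay lower (median log2 fold change −0.33, 0 of 18 called, 9 lower adjusted over the list alone, camera adjusted p = 9.79e-10, adjusted p = 0.417 with an estimated correlation). The ciliated list (−0.30, 12 of 14 lower adjusted over the list alone; camera adjusted p = 1.98e-07, adjusted p = 0.417 with an estimated correlation) also lay lower. So did the goblet cell list (−0.41, 4 of 9; camera adjusted p = 1.77e-04, adjusted p = 0.417 with an estimated correlation) and the club cell list (−0.20, 0 of 12; camera adjusted p = 3.00e-04, adjusted p = 0.509 with an estimated correlation). Without DHA-diet ozone library 1 the median was −0.19 for the ciliated and −0.10 for the club list. Bpifb1, a secreted airway protein, stood at 409 ± 106 and 287 ± 78.0 CPM and Cyp2f2, a club cell oxidase, at 6384 ± 714 and 5179.7 ± 1319. The Cyp2f2 log2 fold change was −0.30, and −0.16 without DHA-diet ozone library 1, which held 2681 CPM. Unfolded protein response genes lay higher (0.17, 8 of 16 adjusted over the list alone; camera adjusted p = 3.81e-06, adjusted p = 0.417 with an estimated correlation), as did extracellular matrix and repair genes (0.22, 3 of 22; camera adjusted p = 1.42e-05, adjusted p = 0.417 with an estimated correlation; median 0.14 without DHA-diet ozone library 1). Platelet markers (0.41, 7 of 8; camera adjusted p = 2.43e-05, adjusted p = 0.417 with an estimated correlation) and erythroid markers (0.95, 5 of 5; camera adjusted p = 3.09e-05, adjusted p = 0.417 with an estimated correlation) lay higher too. Erythroid scores were 4.44, 3.97 and 4.67 log2 CPM in DHA-diet ozone libraries 1, 3 and 4. Libraries 2, 5 and 6 had 3.27, 3.19 and 3.22, within the control-diet ozone range of 2.83 to 3.31. Calr stood at 571 ± 60.5 and 653 ± 68.0 CPM, the platelet integrin Itga2b at 20.9 ± 2.29 and 26.7 ± 4.82, and Alas2, the erythroid enzyme of haem synthesis, at 69.2 ± 15.7 and 138 ± 81.4. Alas2 passed the threshold without DHA-diet ozone library 2 (edgeR Benjamini-Hochberg adjusted p = 0.0373). The neutrophil list had a median log2 fold change of 0.64 (0 of 16 adjusted over the list alone; camera adjusted p = 0.0315, adjusted p = 0.9 with an estimated correlation). Its median was 0.35 without DHA-diet ozone library 1, and without DHA-diet ozone libraries 1 and 2 camera gave it an adjusted p of 0.717 in the lower direction. Oxylipin enzymes (median log2 fold change 0.03, camera adjusted p = 0.893, adjusted p = 0.934 with an estimated correlation) had 0 members called, over all genes or adjusted over the list alone. The same held for oxylipin and fatty acid receptors (−0.03, camera adjusted p = 0.893, adjusted p = 0.934 with an estimated correlation).

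The interaction, which asks of each gene whether ozone changed it by a different amount on the 2 diets, singled out no gene past the threshold. Scn3b, a sodium channel subunit, had the smallest p: it moved by −0.34 ± 0.079 log2 units after ozone on the control diet and by −0.93 ± 0.079 on the DHA diet, and the difference of −0.59 ± 0.11 had an edgeR quasi-likelihood Benjamini-Hochberg adjusted p of 0.166. Etv5 had a difference of −0.44 ± 0.086 (adjusted p = 0.166 in the same edgeR test), Acta2 of 0.54 ± 0.12, Grpel2, a mitochondrial co-chaperone, of −0.32 ± 0.068 and Fchsd2 of −0.31 ± 0.070. Acta2 and Etv5 differed between the diets in air, and the interaction uses the same air libraries. edgeR called 0 genes higher and 0 lower, with 988 at an unadjusted p under 0.05, DESeq2 called 2 and 3, and limma-voom 0 and 2. Scn3b and Etv5 were called by DESeq2 and by limma-voom, and Grpel2 and Acta2 by DESeq2. Scn3b and Acta2 were also called without control-diet air libraries 4 to 6. Of 99 regroupings of the same libraries, the median had 606 genes at an unadjusted p under 0.05 and the highest 2378, and 19 of 100 groupings, the real one included, had at least 988. Without control-diet air library 6, edgeR called 2 and 1, among them Acta2 and Scn3b (Benjamini-Hochberg adjusted p = 0.00863 and 0.00388).

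Platelet markers had a median log2 fold change after ozone of −0.35 on the control diet and 0.27 on the DHA diet. Their median log2 difference was 0.54 (4 of 8 higher adjusted over the list alone, camera adjusted p = 4.18e-07, adjusted p = 0.293 with an estimated correlation). For the interaction 0 lists were called with an estimated correlation and 0 with fry, so the list differences given here rest on camera at the preset correlation. Erythroid (−0.63 and 0.01), adipocyte (−0.55 and −0.14) and cardiac muscle medians (−0.32 and −0.05) also stood higher on the DHA diet. Erythroid scores after ozone on the DHA diet ran from 3.19 to 4.67 log2 CPM, below and above those in DHA-diet air (3.55 to 4.32). Itga2b had a difference of 0.49 ± 0.17 and the chemokine precursor Ppbp of 0.65 ± 0.22. Smooth muscle and pericyte markers had a higher ozone change on the DHA diet than on the control diet (0.28, 6 of 12 adjusted over the list alone; camera adjusted p = 3.12e-05, adjusted p = 0.293 with an estimated correlation). So did neutrophil markers (0.78, 0 of 16 adjusted over the list alone; camera adjusted p = 2.39e-04, adjusted p = 0.612 with an estimated correlation). Alveolar type 2 markers (−0.16, 1 of 14 lower adjusted over the list alone; camera adjusted p = 7.21e-07, adjusted p = 0.367 with an estimated correlation) had a lower ozone change on the DHA diet. Clock genes did too (−0.37, 6 of 17 lower and 1 higher adjusted over the list alone; camera adjusted p = 1.86e-04, adjusted p = 0.293 with an estimated correlation). The clock, alveolar type 2, smooth muscle, adipocyte and cardiac muscle lists differed between the diets in air. The interaction uses the same air libraries. In air the DHA diet had median log2 fold changes of −0.59 for the adipocyte and −0.44 for the cardiac muscle list. On the control diet 1 of 16 neutrophil markers had risen after ozone (camera adjusted p = 0.335), and without DHA-diet ozone libraries 1 and 2 the neutrophil list had an interaction camera adjusted p of 0.309. Inflammatory cytokine and acute-phase genes and chemokines, the groups the study's title is about, had median differences of 0.12 (camera adjusted p = 0.374, adjusted p = 0.822 with an estimated correlation) and −0.02 (camera adjusted p = 0.485, adjusted p = 0.822 with an estimated correlation) with 0 members called. Without 1 library these medians ran from −0.01 to 0.22 and from −0.09 to 0.15. The chemokine median changed sign with library totals and no further scaling, which also moved the median of all genes from 0.001 to 0.0279. Between the diets after ozone their medians were 0.20 (camera adjusted p = 0.407, adjusted p = 0.934 with an estimated correlation) and 0.17 (camera adjusted p = 0.546, adjusted p = 0.934 with an estimated correlation), with 0 members called.

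**Figure D3:**
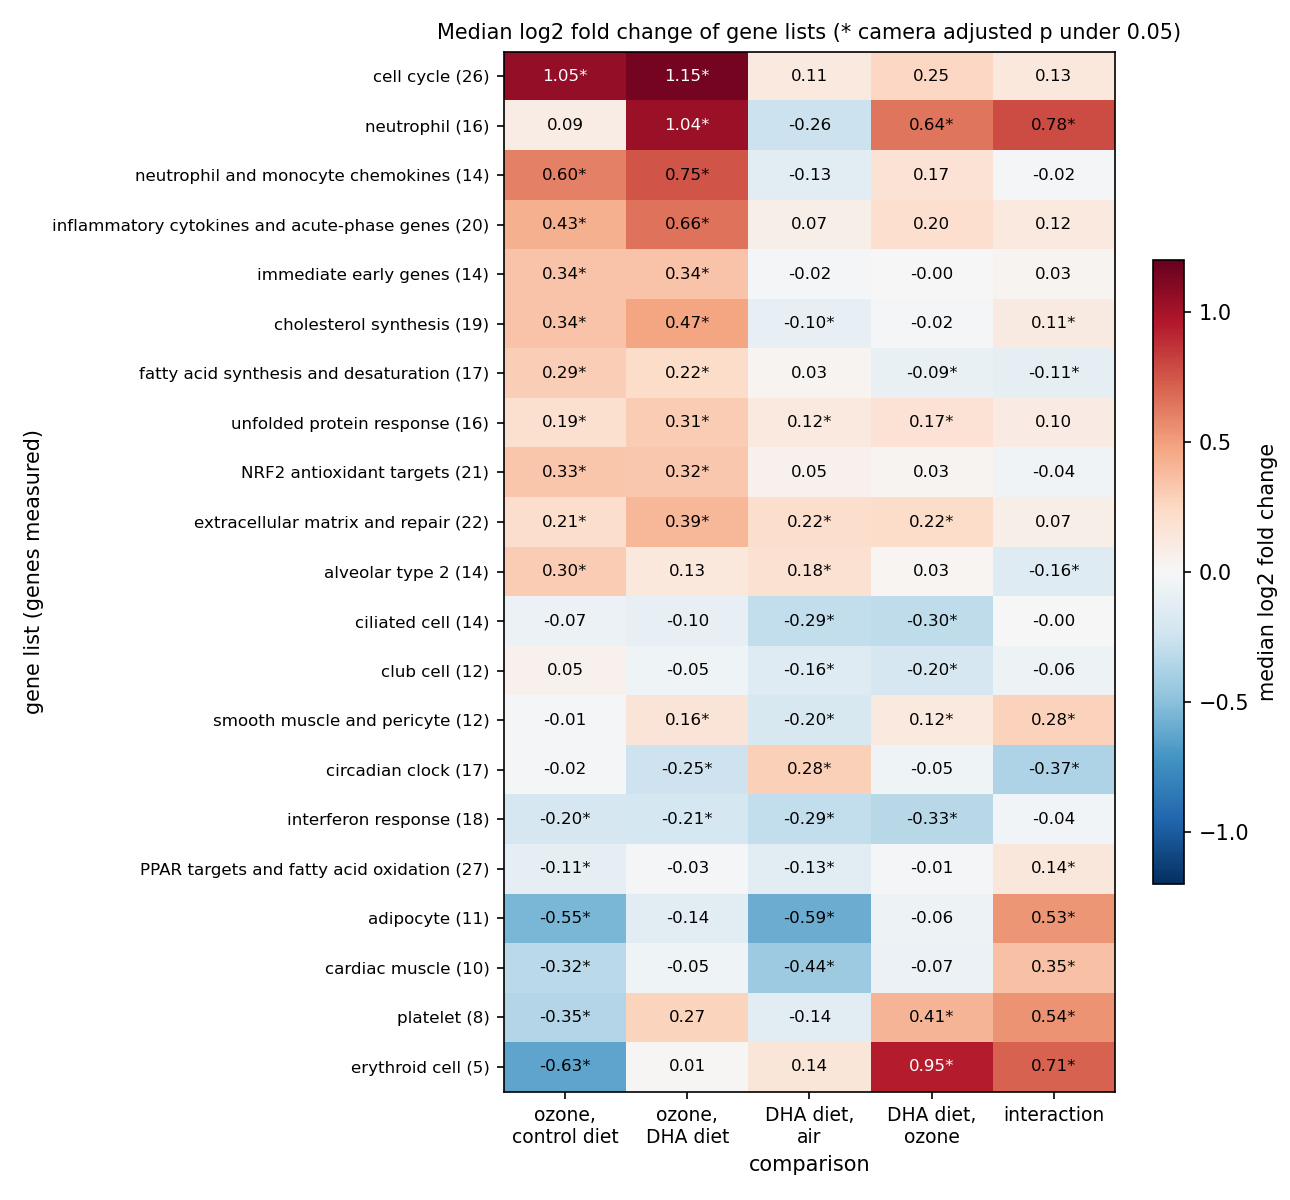
Median log2 fold change of the measured members of 21 gene lists (rows, number of genes measured in parentheses) in the 5 comparisons (columns), with an asterisk where camera with a preset correlation gave an adjusted p under 0.05. The cell cycle list stands highest in both ozone comparisons (1.05 and 1.15), and the interferon response list is negative in all 5 columns.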

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

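The tests with ribosomal protein transcripts, with control-diet air libraries 1 to 3, of Clca1 against the ciliated list, of the splits for diet in air, diet after ozone and the interaction, and of counts at an unadjusted p in splits were chosen after the results were seen. Among 292 groups of 6 libraries over 73 named genes, 23 values lay far from the other 5 by Dixon's gap test, where chance gives about 1 in 20 groups, or 14.6. Of these, 18 were high and 5 low.

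DHA-diet ozone library 1 held 8 of the 23. There Saa3 stood at 64.1 CPM (others 3.79 to 16.5), Sprr1a at 26.7 (3.84 to 10.4), Nfil3 at 13.6 (5.06 to 7.73), Ptges at 53.4 (28.3 to 37.2) and Fkbp5 at 69.3 (29.6 to 41.8). Calml3 at 2.77 (6.94 to 9.07), Nr1d2 at 107 (152 to 177) and the club cell oxidase Cyp2f2 at 2681 (4987 to 6349.5) were low. The same library had the highest neutrophil score (3.72 log2 CPM) and the lowest ciliated (5.28) and club scores (8.47) of the 24. In DHA-diet ozone library 2 Taldo1 stood at 319, and in library 5 Ifi44 at 9.10.

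Control-diet air library 5 held 3: the neutrophil genes Retnlg (5.13 CPM) and Clec4d (5.33), and Cdc42ep4 (141). Control-diet air library 4 was high for Alb (1.96) and library 6 for Scn3b (82.0). Control-diet ozone library 6 was high for Pck1 (8.03) and Osm (4.07), library 4 for Grpel2 (37.3), and library 5 was low for Cry1 (12.05). In DHA-diet air, library 5 was high for Saa3 (5.23), library 3 for Pck1 (12.6) and library 1 for Bcan (10.4), and library 4 was low for Nr1d2 (179).

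The 186 genes that differed between diets in air were weighed against 5 technical explanations by the ratio of their median absolute log2 fold change with and without each. Batch or processing order was not among them. The library names run group by group, so an order that follows them cannot be told apart from diet. The same holds for the other comparisons. Library size (0.933) and ribosomal protein transcripts as a reading of quality (0.967) each left most of the change. This argues against a linear trend with each of these 2 as the whole cause. Whether ribosomal protein transcripts follow RNA quality in these libraries was not tested. Clock genes as a reading of collection time gave 1.06, with a covariate drawn from the clock list over all 24 libraries, ozone libraries included. Whether that covariate follows the clock shift between the diets in air was not tested, so its ratio cannot decide about collection time. Leaving out control-diet air libraries 1 to 3 gave 0.843. The genes had been called with those libraries in the fit, so this ratio cannot decide about them. Called genes numbered 42 higher and 11 lower with library size, 773 and 766 with clock genes, and 126 and 49 with ribosomal protein transcripts, against 117 and 69. Without those 3 libraries 0 genes were called in edgeR's quasi-likelihood test, with fewer libraries and a median of 0.843 times the size. Muscle and fat scores took the ratio to 0.659 (median 0.34 to 0.23, all 186 with the same sign, 0 called), so muscle and fat tissue taken along cannot be told apart from an effect of diet on the lung, which stays open. Of 100 splits of the 12 air libraries only the real one gave as many genes (1 of 100, 186 against 163 at most), a share under the bound set for these splits. The margin is narrow: the split with 163 had 2932 genes at an unadjusted p under 0.05, against 2798 for the real one (2 of 100 with as many). That split had moved 6 of the 12 libraries. A grouping that mixed the diets thus gave nearly as many calls, so chance is not excluded for this count.

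The 2737 genes lower after ozone averaged over diets kept 0.883 of their median log2 fold change once trends with GC content and transcript length were removed (−0.25 to −0.22), which argues against those trends as the whole cause. Cold-induced transcripts, read as a sign of lower body temperature, were higher in 0 of 4 pairs of gene and diet. For ozone, the real split was the 1 of 100 with as many genes on each diet. The counts were 2713 against 125 at most on the control diet and 3824 against 1317 at most on the DHA diet. This argues against chance as the source of both counts if the libraries came from separate mice, which the labels do not say. An effect of ozone stays open as the biological explanation.

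The airway lists that lay lower with the DHA diet after ozone may reflect less conducting airway in the tissue taken: within groups the ciliated and club scores rose and fell together over the 24 libraries (Pearson correlation 0.955, Spearman 0.848, permutation p = 1e-05, the smallest 100000 permutations can give, and 0.891 without the 2 farthest libraries). The medians after ozone went from −0.30 to −0.19 (ciliated) and from −0.20 to −0.10 (club) without DHA-diet ozone library 1. Airway cells changed together by ozone would also make these scores rise and fall together, so the correlation cannot tell that from less airway taken. Clca1 lay −4.73 of its standard errors from the median of the ciliated list. It is a goblet cell gene singled out after its values were seen, so this distance cannot decide about the same explanation for Clca1. For diet after ozone all 100 of 100 splits gave as many genes as the real 0 (3 at most), and for the interaction 100 of 100 (0, and 4 at most), but every split gives at least 0, so these counts decide nothing about chance. At an unadjusted p under 0.05, 2 of 100 splits had as many genes as the real 2260 for diet after ozone (2481 at most). That share is under the bound set for these splits, but the count was chosen for testing after 0 genes had been called. Chance is therefore not excluded for it. For the interaction 19 of 100 had as many as the real 988 (2378 at most), so chance stays open there. DESeq2 called 38 and 37, and 2 and 3, higher and lower.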

How the results depend on the processing

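Leaving out control-diet air libraries 1 to 3, control-diet air libraries 4 to 6, or DHA-diet ozone libraries 1 and 2 was chosen after the data were seen. Of 960 values of 80 called pairs of a gene and a comparison under settings other than leaving out 1 library, 938 kept their direction and call, 22 kept their direction without the call and 0 reversed. With 1 library left out, 1890 of 1920 kept the call, 30 kept the direction alone and 0 reversed, and of 713 values of uncalled pairs 47 passed the threshold and 0 reversed. RLE scaling, no filter, 1 CPM in 6 libraries and 1 surrogate variable left every count of called genes within 1.5 times its value. The cause of the changes below was not tested, except that stricter thresholds call fewer genes by construction.

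Counts are given as higher and lower. At an adjusted p under 0.01, ozone gave 705 and 540 genes on the control diet and 1191 and 910 on the DHA diet, with 527 and 347 shared, and diet in air gave 16 and 4. With a fold of at least 2 the counts were 104 and 35, 167 and 65, and 3 and 1. With library totals and no further scaling, ozone on the control diet gave 940 higher and diet in air 72 and 113. DESeq2 gave 317 and 272 for diet in air, 38 and 37 for diet after ozone, and 2 and 3 for the interaction. limma-voom with quality weights gave 408 and 441, 8 and 11, and 0 and 2. A fit of the 2 groups alone gave 187 and 172 for diet in air and 1 and 1 for diet after ozone. With the replicate number as a block, diet in air gave 64 and 21. Without control-diet air libraries 1 to 3, ozone on the control diet gave 852 higher and diet in air 0 and 0. Without control-diet air libraries 4 to 6, diet in air gave 655 and 896, diet after ozone 12 and 15, and the interaction 3 and 1. Without DHA-diet ozone libraries 1 and 2, diet in air gave 344 and 403.

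With an estimated correlation, camera called 0 lists in each of the 5 comparisons, against 19, 13, 19, 17 and 14 with the preset correlation. fry called 18 and 15 lists for ozone on the 2 diets, 4 for diet in air, 1 for diet after ozone and 0 for the interaction. With 1 library left out, counts ran from 1084 to 1497 and 941 to 1552 for ozone on the control diet, 1687 to 2241 and 1388 to 1827 for ozone on the DHA diet, 37 to 308 and 12 to 439 for diet in air, 0 to 71 and 0 to 73 for diet after ozone, and 0 to 2 and 0 to 1 for the interaction. The diet difference in response size ran from 0.0149 to 0.0414 log2 units. Of the smallest simulated changes, 36 to 54% were recovered between groups and 16% for the interaction, at this depth and number of libraries. Depth itself was not varied.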

Other observations

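The tests of the glycolysis and splicing lists were chosen after the leading genes had been seen, so they cannot decide whether either list moved as a group. Of 16 glycolysis enzymes, 7 were called higher and 1 lower after ozone on the control diet (11 and 2 adjusted over the list alone, median log2 fold change 0.20). On the DHA diet 12 were called higher (12 and 1 adjusted over the list alone, median 0.25). The larger of the 2 camera p-values was 6.51e-06, and p = 0.00994 and 0.00149 with an estimated correlation, on genes picked after the pattern was noticed.

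Of 14 SR proteins, which select splice sites, and Clk kinases that phosphorylate them, 4 were called lower after ozone on the control diet (6 adjusted over the list alone). On the DHA diet 5 were called lower and 1 higher (6 and 1 adjusted over the list alone), with a median log2 fold change of −0.12 on each diet. The larger of the 2 camera p-values was 0.00278, and p = 0.174 and 0.135 with an estimated correlation, on genes picked in the same way, so this stays open too.

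Diet effects in air and after ozone, which use different libraries and 1 estimate of the spread, had a Pearson correlation of 0.322 over all 16153 genes, of which 64.1% had the same sign. Over the 186 genes called in air, chosen for their size there, it was 0.8 with 89.2%. Glucocorticoid-responsive genes lay higher with the DHA diet after ozone (median log2 fold change 0.21, 0 of 15 called, 2 adjusted over the list alone, camera adjusted p = 0.00199, adjusted p = 0.452 with an estimated correlation). Dendritic cell markers lay higher with the DHA diet in air (0.26, 1 of 12 called, 2 adjusted over the list alone, camera adjusted p = 4.61e-04, adjusted p = 0.352 with an estimated correlation; median 0.15 without DHA-diet air library 1).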
